A study of Mus musculus with 4 samples.

How the data were processed

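RNA-seq was deposited for jejunal epithelium of adult mice of a mixed 129xC57/Bl6xSvJ background. There were 4 libraries, 2 from Cre-negative controls and 2 from mice labelled as Hnf4a;Cdx2 double knockouts, which the labels call independent biological replicates. Per the labels' protocols, every mouse received 1 mg of tamoxifen on 5 days, and the epithelium was released with 5 mM EDTA for 45 minutes at 4 °C. RNA was extracted with TRIzol and RNeasy columns, and TruSeq libraries were read as single-end reads of 75 bases. The protocols do not state whether the libraries kept strand. Groups and replicate numbers were taken from the sample titles.

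Per the submitters' processing notes, TopHat2 version 2.0.9, Cufflinks version 2.1.1, Cuffnorm, Cuffdiff and the mouse build mm9 were used; the notes give these names without roles. The authors deposited a table of 23735 rows with 1 column per library, whose header names no unit. It was taken as FPKM (fragments scaled to transcript length and library size) normalized between the libraries, because its values resemble the FPKM of the other deposited files and Cuffnorm is named in the notes. The authors also deposited 1 file per library with 24460 rows of FPKM estimated for that library alone, with interval bounds and an estimation status, per the file headers. In 1972 to 2791 rows per library the FPKM lay outside its own interval, so these bounds were not used as errors. The table of the authors' comparison holds, per the file headers, a group FPKM for each genotype, a test statistic score, p-values and q-values, a test status and a call. Its column of log2 fold changes was not used here, since some of its cells hold a spreadsheet error in place of a value. Direction in that table was taken from its group values.

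The files used here hold no read counts, so the depth of each library is unknown and no counting error or detection floor is given. The values of a library summed to between 643708 and 689276 FPKM, and 10635 to 10749 symbols had at least 1 FPKM. The 10 most abundant symbols held 15.7% to 19.6% of the summed FPKM. Because a value listed at 0 can be a failed estimate (Hmgcs1, a gene of cholesterol synthesis in most cells, is listed at 0 in all 4 libraries), such genes are given as listed at 0 and no fold is given against them.

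Rows that share a symbol were summed (147 symbols), and 1036 symbols that name short RNAs (Mir, Snor, Scarna) were left out. Genes with a mean of at least 1 FPKM over the 4 libraries were tested, 10883 in all. The test was limma (version 3.58.1, in R version 4.3.3) on log2(FPKM + 1), with genotype as the term and an intensity trend in the empirical Bayes step, two-sided. Benjamini-Hochberg adjustment ran over all genes tested, and genes were called at an adjusted p under 0.05. Fold changes on this scale understate the change of low genes. All adjusted p-values for genes are from limma, and an exact permutation test of 2 libraries against 2 cannot give a p under 0.333.

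There were 31 gene lists with 819 entries, written from textbook knowledge before the data were examined, as were the design, the alternatives and the rule for named genes. Of the entries, 808 were found in the table, 10 of them in rows that join several symbols. The 28 lists with at least 5 tested members were tested with limma's camera against all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, a rotation test of whether a list moves on balance in 1 direction, were alternatives. With an estimated correlation camera rests on the few residual degrees of freedom of 4 libraries. Its lowest unadjusted p over the lists was 0.0624 (enteroendocrine cells). That version therefore has little power here, and its lack of a call does not decide for or against a list. Counts "adjusted over the list alone" use Benjamini-Hochberg adjustment within that list. The genes named were fixed by rule: Cdx2, Hnf4a, Cdx1, Hnf4g, Gata4 and Gata6 whatever their values; the 8 called genes with the highest rise and the 8 with the deepest fall whose groups did not overlap, leaving out unnamed loci; and from each list the 2 called members with the greatest change in its main direction, in both directions where the smaller held at least 3. The rule did not foresee lists with as many members called higher as lower (Paneth cells, goblet cells, antimicrobial and inflammatory response, cell junctions and keratins); for these both directions were named, a choice not fixed before the data were examined. From a list with no called member the most abundant one was named. Other genes outside this rule are marked as chosen after their values were seen.

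The alternatives changed the pseudocount, the filter on low values, the scaling between libraries, the source of the FPKM, the variance model, a limit on the fold change, a replicate block and the set test, and left out each library in turn. The procedure was tested on simulated data with the means and spread of the 10883 genes. It recovered 5.97% of genes changed by 1 log2 unit, 57.6% of those changed by 2 and 81.5% of those changed by 4 over 5 runs. It called 0.0338% of unchanged genes. In these runs a gene with a modest difference was often missed with 2 libraries per group. Far fewer genes were changed in each run than the 1041 called in the data. The Benjamini-Hochberg cutoff was therefore stricter in the simulation, so neither the recoveries nor the rate of false calls carries over to the data. A list shifted by 1 log2 unit was called in 5 of 5 runs, with 1 call of another list in all runs together. The simulated genes varied independently of each other. In the data the estimated correlation between members reached 0.926 (tuft cells) and 0.895 (cell cycle), so the simulated rate of false list calls does not carry over to such lists.

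Coordinates are those of the authors' files, build mm9, written from base 1. The reference annotation at hand was of another build and was not used. Genes with near-identical copies (the Defa, Gsta, Cyp2c, Cyp3a and H2 families) are uncertain, because reads of 75 bases can be split between copies, and overlapping or antisense genes are uncertain without strand; 181 tested rows join several symbols.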

Results

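The data comprised 4 RNA-seq libraries of jejunal epithelium from adult mice, 2 from controls without Cre and 2 from animals labelled as double knockouts of Hnf4a and Cdx2 after tamoxifen. Both genes encode transcription factors of the intestinal epithelium. The values were FPKM, so the depth of each library is unknown. Across the 10883 genes tested, log2 values correlated at r = 0.971 between the control libraries and at r = 0.961 between the double knockout libraries, against 0.884 to 0.904 between the groups. These correlations are across genes, which are not independent replicates. All 4 libraries held little Xist (0.0170 to 0.0666 FPKM) and 7.41 to 10.4 FPKM of the Y-linked gene Ddx3y. The single comparison asked which genes differ in the jejunal epithelium when both factors are targeted together.

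The targeted genes came first, as a check of the labels. Hnf4a (chromosome 2, 163372924 to 163398643, mm9) fell from 179 ± 32.4 FPKM in controls to 39.9 ± 11.8 in double knockouts (SD, n = 2 each), a log2 fold change of -2.16 ± 0.27 (SE, limma, adjusted p = 0.0147). Cdx2 (chromosome 5, 148112476 to 148118825) rose from 68.1 ± 4.04 to 160 ± 0.888 FPKM (SD, n = 2 each), a log2 fold change of 1.23 ± 0.15 (SE, limma, adjusted p = 0.0150). This direction goes against the label for Cdx2. A gene-level FPKM includes exons outside a deleted part, and the deleted exons are not given in the sources used here, so these values do not show whether Cdx2 was deleted. The mutant group is therefore called the libraries labelled double knockout, and every direction given for it rests on the labels. In the authors' deposited table both genes were also called, Hnf4a at 181 FPKM in control and 40.0 in the knockout (q = 0.000868) and Cdx2 at 74.0 and 169.9 (q = 0.00515). Among their relatives, Hnf4g, the paralog of Hnf4a, fell from 204 ± 48.3 to 69.3 ± 16.2 FPKM (SD, n = 2 each, limma, adjusted p = 0.0315). Cdx1 stood at 79.7 and 77.5 FPKM, Gata4 at 38.4 and 38.6 and Gata6 at 28.5 and 30.9 in control and labelled double knockout, with limma adjusted p-values of 0.933, 0.978 and 0.769. Leaving out control replicate 2 raised the limma adjusted p to 0.0875 for Hnf4a, 0.0868 for Cdx2 and 0.126 for Hnf4g. Without control replicate 1 these were 0.0624, 0.0696 and 0.0756, and without double knockout replicate 2 Cdx2 and Hnf4g stood at 0.0602 and 0.106.

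**Figure D1:**
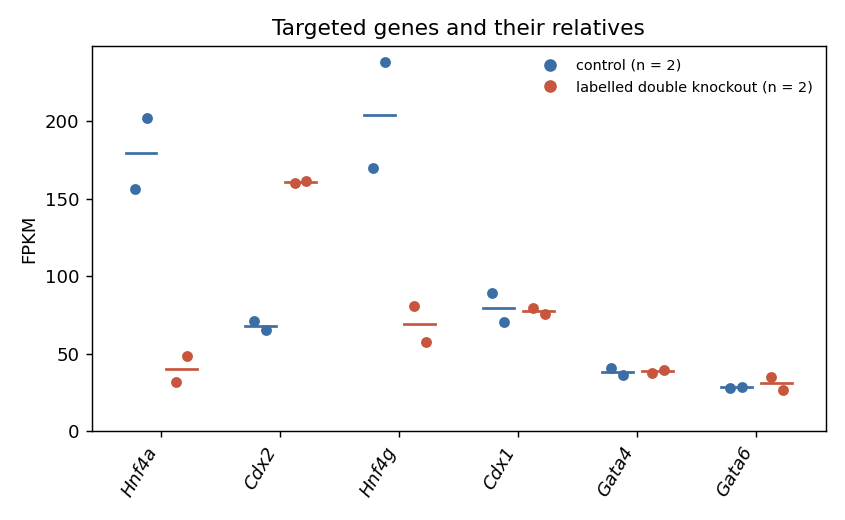
FPKM of the targeted genes and their relatives in each library, on a linear axis; points are libraries and short lines are group means (n = 2 each). Hnf4a was lower in both libraries labelled double knockout (31.6 and 48.2 FPKM against 156 and 202), and Cdx2 was higher (160 and 161 against 70.9 and 65.2).

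In the libraries labelled double knockout 17 of 18 tested genes of the stomach epithelium list rose and 11 of 19 brush border enzyme genes fell (camera, adjusted p = 5.86e-15 and 4.19e-08, and adjusted p = 0.642 for both with an estimated correlation). Limma called 1041 genes, 410 higher and 631 lower. Of these, 872 differed by at least 1 log2 unit (343 higher and 529 lower). In each called gene the groups did not overlap, which chance gives in 33.3% of all genes with 2 libraries against 2. A call favours genes whose groups separate, so this separation adds no support. The split of calls depended on the source of the FPKM. Values estimated for each library alone, with 10718 genes tested, gave 515 higher and 478 lower. The median of all genes was then at 0.17 on the log2 scale against 0.02 here. Rescaling the same values kept the split, with 410 higher and 615 lower after median centring and 424 and 622 after quantile normalization. The number called fell to 171 without control replicate 1, 176 without control replicate 2, 693 without double knockout replicate 1 and 506 without double knockout replicate 2. The authors' deposited table calls 1532 genes, 684 higher and 848 lower in the knockout. Of the 1458 that were tested here, all had the same direction here and 869 were also called by limma. That table was computed from the same libraries, so the shared directions and calls are not independent evidence. Of the 66 genes named by rule, ties included, and called by limma, the authors' deposited table calls 55, and it does not call Gkn1, Gkn2, Tff2, Dnase1, Tmigd1, Fdft1, Epcam, Tpsg1, Pdx1, Ddit3 and Ctrb1.

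Ranked by log2(FPKM + 1), which sets genes with low levels lower than a ratio of FPKM would, the 8 highest rises were in genes that were scarce in controls. Gkn2 and Gkn1, gastrokines secreted by gastric surface mucous cells, rose from 0.0431 ± 0.0609 to 1275 ± 727 FPKM and from 0.106 ± 0.150 to 817 ± 431 FPKM (SD, n = 2 each, limma, adjusted p = 0.00133 for both). Tff2, a trefoil peptide of gastric mucus, rose from 0.0675 ± 0.0955 to 322 ± 110 FPKM, and Gkn3 from 1.82 ± 0.503 to 169 ± 38.5 (limma, adjusted p = 0.00133 for both). Ly6d reached 707 ± 125 FPKM against 1.42 ± 1.14, Sult1c2, a sulfotransferase, 305 ± 37.2 against 2.11 ± 1.05, Lyve1, known as a hyaluronan receptor of lymphatic endothelium, 183 ± 34.6 against 1.70 ± 0.218, and Ttr, the thyroid hormone carrier transthyretin, 192 ± 69.9 against 2.32 ± 0.686. All 8 kept their call when any 1 library was left out. The authors' deposited table calls the others but not Gkn1 (q = 0.338), Gkn2 or Tff2 (q = 0.534 for both), although its group values for them are 751, 1293 and 308.9 FPKM in the knockout.

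The stomach epithelium list held 18 tested members, of which 17 rose and 1 fell; the counts were the same adjusted over the list alone. The filter on the mean of all libraries favours members that rose: 12 of the 17 had a control mean under 1 FPKM, and 11 of the 29 members in the table lay under the filter. With no filter but a mean above 0, 14 of 23 members rose and 1 fell, at a median log2 fold change of 3.33 (camera, adjusted p = 6.94e-15). Its median log2 fold change was 3.95 (camera, adjusted p = 5.86e-15, and adjusted p = 0.642 with an estimated correlation). Among the members that rose were Anxa10 (56.5 FPKM against 0.0312) and Pgc, the precursor of a gastric protease (28.8 against 0.269), both chosen after their values were seen. The authors' deposited table calls Pgc (q = 0.0230) but not Anxa10 (q = 0.563) or Cym (q = 0.571). Vsig1 and Aqp5 were listed at 0 in both controls and reached 11.1 to 21.0 and 7.39 to 10.97 FPKM per library. Cym, the gene of the milk-clotting protease chymosin, fell from 5.37 ± 2.47 to 0.0366 ± 0.0518 FPKM (SD, n = 2 each, limma, adjusted p = 0.0150). Other gastric genes on the list stayed under the filter. Gast, Tff1, Lipf and Sox2 were listed at 0 in every library, and Muc5ac and Muc6 did not exceed 0.0308 FPKM. Vsig1, Aqp5, Cym and the genes under the filter were also chosen after their values were seen.

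**Figure D2:**
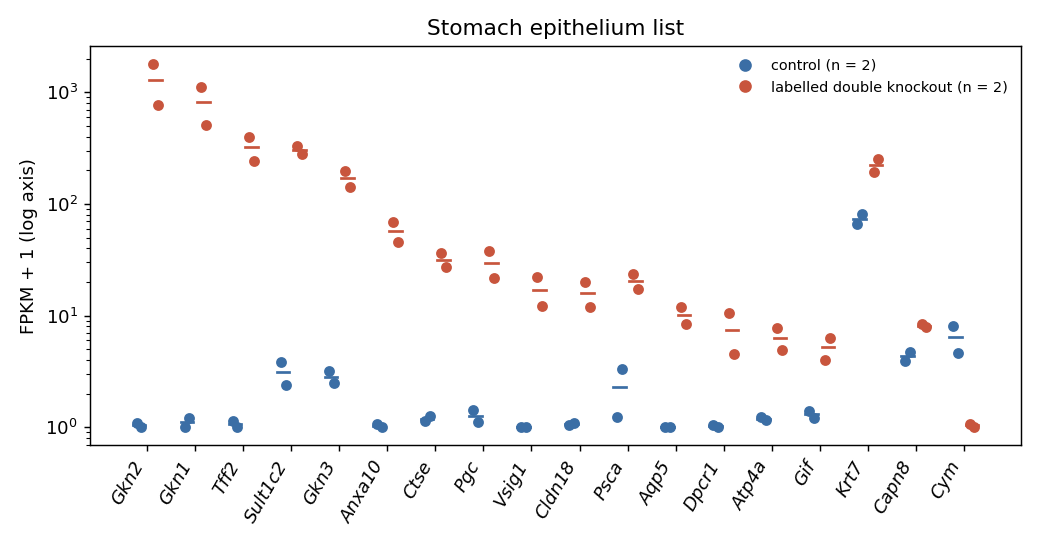
FPKM + 1 on a log axis for the 18 tested members of the stomach epithelium list, ordered by fold change; points are libraries and short lines are group means (n = 2 each). The 17 members that rose lie above both controls in both libraries labelled double knockout, and Cym lies below.

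Of the 19 tested brush border digestive enzymes 11 fell and 0 rose, with 13 lower adjusted over the list alone, at a median log2 fold change of -2.25 (camera, adjusted p = 4.19e-08; adjusted p = 0.642 with an estimated correlation). Of the 8 not called, Anpep, Alpi and Akp3 had log2 fold changes above 0 (0.50, 0.78 and 0.78; limma, adjusted p = 0.248, 0.178 and 0.451) and were chosen after their values were seen. Enpp7, which digests sphingomyelin, fell from 281 ± 39.6 to 0.933 ± 0.602 FPKM, and Lct, the lactase gene (chromosome 1, 130181341 to 130224895), from 292 ± 12.0 to 1.72 ± 1.38 (SD, n = 2 each, limma, adjusted p = 0.00133 and 0.00233). On the log2(FPKM + 1) scale these were the 2 deepest falls among the named genes, followed by Dnase1 (180 ± 87.2 to 1.14 ± 0.720), the sugar transporter family member Slc5a4b (84.6 ± 19.3 to 0.631 ± 0.119), H2-Bl (581 ± 19.7 to 16.9 ± 19.6), Prss30 (64.7 ± 4.90 to 0.479 ± 0.425), the dipeptidase gene Dpep1 (258 ± 71.5 to 4.98 ± 2.67) and Gal3st2 (95.5 ± 10.7 to 1.21 ± 0.0233). H2-Bl belongs to a family of near-identical genes and its level is uncertain; its call was lost without either control (limma, adjusted p = 0.122 and 0.142).

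Transporters and microvillus genes were lower as lists. For sugar, amino acid, metal and vitamin transporters 7 of 26 members fell and 0 rose (9 lower and 2 higher adjusted over the list alone, median -0.84, camera, adjusted p = 1.92e-05, adjusted p = 0.642 with an estimated correlation). The amino acid transporter Slc6a20a fell 16.6-fold and the glutamate transporter Slc1a1 16.0-fold. For microvillus structure 3 of 21 members fell and 1 rose (13 lower and 2 higher adjusted over the list alone, median -0.64, camera, adjusted p = 0.000172, adjusted p = 0.642 with an estimated correlation). Tmigd1 fell from 12.2 ± 5.00 to 0.172 ± 0.124 FPKM (SD, n = 2 each) and Myo7b, a myosin of the microvillus tip, fell 2.29-fold (limma, adjusted p = 0.00805 and 0.0181). The member that rose was Baiap2l1 (32.2 to 60.3 FPKM), chosen after its value was seen. Myo7b lost its call without control replicate 1 or 2 or double knockout replicate 2 (limma, adjusted p = 0.0861, 0.0865 and 0.0754).

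Lipid absorption and chylomicron assembly was lower as a list, with 2 members called lower and 1 higher of 27 (7 lower and 1 higher adjusted over the list alone, median -0.51, camera, adjusted p = 0.00380, adjusted p = 0.847 with an estimated correlation). Abcg5, a sterol exporter, fell from 164 ± 19.9 to 53.9 ± 24.0 FPKM, and Pla2g12b from 130.4 ± 3.25 to 52.4 ± 8.02 (SD, n = 2 each, limma, adjusted p = 0.0484 and 0.0176). Both lost their call without either control or without double knockout replicate 2, with limma adjusted p-values of up to 0.157 and 0.0971. Scarb1, a lipoprotein receptor chosen after its value was seen, rose from 2.35 to 34.9 FPKM. Cholesterol synthesis genes rose, 7 of 22 with 0 falling (16 higher and 1 lower adjusted over the list alone, median 0.90, camera, adjusted p = 1.02e-05, adjusted p = 0.642 with an estimated correlation). Sqle and Fdft1, enzymes of the squalene steps, rose 4.30-fold and 2.65-fold (limma, adjusted p = 0.00990 and 0.0128). Their calls were lost without control replicate 1 (limma, adjusted p = 0.0562 and 0.0691), and that of Fdft1 also without control replicate 2 (0.0656) or double knockout replicate 2 (0.0620). For fatty acid oxidation and ketogenesis 4 members fell and 1 rose of 28 (7 lower and 4 higher adjusted over the list alone); the median was -0.21 and the mean 0.06, of opposite sign, and the list was not called (camera, adjusted p = 0.299). Hadh fell 2.92-fold and Crat 2.38-fold, each losing its call without either control or without double knockout replicate 2 (limma, adjusted p of up to 0.0995 and 0.0868).

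Genes of xenobiotic metabolism moved in both directions, with 11 lower and 4 higher of 34 (14 lower and 6 higher adjusted over the list alone, median -0.83, camera, adjusted p = 0.0158, adjusted p = 0.642 with an estimated correlation). Gsta4, a glutathione transferase, rose from 84.4 ± 18.3 to 2185 ± 56.2 FPKM and Gsta1 from 64.6 ± 10.1 to 504 ± 41.1 (SD, n = 2 each, limma, adjusted p = 0.00164 and 0.00369); reads may be shared within that family. Abcb1a, a drug efflux pump, fell 21.9-fold and Cyp2j6 7.46-fold, to 19.6 ± 4.76 FPKM (SD, n = 2) from 146 ± 36.4 (limma, adjusted p = 0.00203 and 0.00809). Cyp2j6 reached a limma adjusted p of 0.0540 without control replicate 2.

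The enteroendocrine cell list holds hormones, granins, processing enzymes and transcription factors. Of its 20 tested members 10 fell and 0 rose (17 lower adjusted over the list alone, median -1.23, camera, adjusted p = 8.78e-10, adjusted p = 0.642 with an estimated correlation). Nts, the neurotensin gene, fell from 105 ± 13.1 to 3.71 ± 0.762 FPKM and Sct, the secretin gene, from 115 ± 5.39 to 19.6 ± 2.62 (SD, n = 2 each, limma, adjusted p = 0.00137 and 0.00388), and both kept their call when any 1 library was left out. Other hormone genes of the list were not called, among them Pyy (12.2 and 12.6 FPKM) and Ghrl (49.0 and 37.2; limma, adjusted p = 0.882 and 0.554), chosen after their values were seen. The other secretory lists were not called. In the goblet cell list Ern2 rose and Tpsg1 fell, 1 each of 24, with the same counts adjusted over the list alone (camera, adjusted p = 0.988; median -0.07 and mean 0.10, of opposite sign). In the Paneth cell list Kcnn4 rose 2.76-fold and Mptx2 fell 12.3-fold, 1 each of 21, with the same counts adjusted over the list alone (camera, adjusted p = 0.804, higher, against a lower direction with fry). In the tuft cell list Ltc4s fell 2.90-fold, 1 of 19, again with the same count adjusted over the list alone (camera, adjusted p = 0.804, lower, against a median of 0.03). The calls of Ern2, Tpsg1 and Kcnn4 were lost whichever library was left out (limma, adjusted p of up to 0.0754, 0.158 and 0.145), and that of Ltc4s was lost in each such fit except the 1 without double knockout replicate 1 (up to 0.0656). The tuft list depended on the controls: it was called lower without control replicate 1 (camera, adjusted p = 1.63e-05) and higher without control replicate 2 (camera, adjusted p = 4.3e-05).

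Of the 3 regional lists 1 was called. Ileum enriched genes fell in 6 and rose in 2 of 13 members (7 lower and 2 higher adjusted over the list alone, median -0.96, camera, adjusted p = 0.0158, adjusted p = 0.642 with an estimated correlation), and the call was lost without control replicate 1 (camera, adjusted p = 0.0575). Slc5a8 fell from 17.3 ± 4.40 to 0.0847 ± 0.0160 FPKM and Cubn, part of the vitamin B12 receptor, from 25.6 ± 18.9 to 0.623 ± 0.506 (SD, n = 2 each, limma, adjusted p = 0.00251 and 0.0213). Cubn reached a limma adjusted p of 0.0879 without double knockout replicate 2, 0.0565 without control replicate 1 and 0.0529 without double knockout replicate 1. Members that rose were Abcc3 and the bile acid transporter Slc10a2, chosen after their values were seen (19.7 to 67.1 and 0.836 to 4.96 FPKM). Duodenum enriched genes rose in 3 and fell in 1 of 15 (5 higher and 4 lower adjusted over the list alone) and were not called (camera, adjusted p = 0.804, higher, against a median of -0.01). Bcmo1, which cleaves beta-carotene, rose from 2.54 ± 0.626 to 94.9 ± 54.4 FPKM, and Pdx1, a transcription factor of the duodenum and pancreas, from 0.515 ± 0.0217 to 7.74 ± 0.398 (SD, n = 2 each, limma, adjusted p = 0.00809 and 0.00435). Pdx1 (chromosome 5, 148081707 to 148086725) lies close to the targeted gene Cdx2 (148112476 to 148118825). Whether its rise is a local effect of the targeted locus was not tested. Colon epithelium genes fell in 3 and rose in 1 of 11 (6 lower and 1 higher adjusted over the list alone, camera, adjusted p = 0.158). Car4 fell 44.6-fold, from 209 ± 148 to 4.68 ± 3.31 FPKM, and Mettl7b 4.48-fold, from 46.9 ± 5.08 to 10.5 ± 6.90 (SD, n = 2 each). Without either control the limma adjusted p was 0.0503 and 0.0676 for Car4, 0.153 and 0.168 for Mettl7b, and 0.0575 and 0.0655 for Bcmo1. The colon list was called lower without control replicate 1, with a filter of 5 FPKM and with FPKM of each library alone (camera, adjusted p = 0.0453, 0.00860 and 0.0359), and the duodenum list turned direction under several alternatives without a call.

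Genes of fetal or regenerating epithelium rose in 4 of 19 with 0 falling (10 higher adjusted over the list alone, median 1.44, camera, adjusted p = 0.000573, adjusted p = 0.642 with an estimated correlation). Under the filter lay 8 of the 27 members that the table holds. With no filter but a mean above 0, 2 of 25 rose (Anxa3 and Emp2) and 1 fell (Ereg, limma, adjusted p = 0.0481, chosen after its values were seen), at a median of 0.77 (camera, adjusted p = 0.000169). Anxa3 rose from 5.74 ± 0.393 to 55.4 ± 0.162 FPKM (SD, n = 2 each) and Emp2 rose 9.36-fold (limma, adjusted p = 0.00164 and 0.0165). Emp2 lost its call without either control (limma, adjusted p = 0.0820 and 0.0965). The cell cycle list was called higher (camera, adjusted p = 0.0367; adjusted p = 0.982 with an estimated correlation) although limma called 0 of its 36 members, over all genes or adjusted over the list alone, with 1 higher at an unadjusted p under 0.05. Its most abundant member, Pcna, stood at 87.8 and 83.3 FPKM. That call was lost with quantile normalization (0.0582), with FPKM of each library alone (0.123) and without double knockout replicate 2 (0.683), and without control replicate 2 the direction turned (0.527). In the crypt base stem cell list Aqp4 and Prom1 rose 3.27-fold and 2.46-fold, 2 of 20 with the same count adjusted over the list alone (camera, adjusted p = 0.519), and both calls were lost without control replicate 2 (limma, adjusted p = 0.0786 and 0.164). The call of Aqp4 was also lost without either double knockout replicate (0.138 and 0.132), and that of Prom1 without control replicate 1 (0.139) or double knockout replicate 1 (0.0851). Without control replicate 1 this list was called higher (camera, adjusted p = 0.0120). Among 35 intestinal transcription factors 4 rose and 5 fell (6 each adjusted over the list alone, camera, adjusted p = 0.528). Pparg rose 3.96-fold and Vdr, the vitamin D receptor, fell 4.95-fold (limma, adjusted p = 0.0182 and 0.00805), with adjusted p-values of 0.0820 and 0.0543 without control replicate 1; Pparg also lost its call without control replicate 2 (0.0656) or double knockout replicate 2 (0.0727). In the list of junctions and keratins 2 rose and 2 fell of 28, with the same counts adjusted over the list alone (camera, adjusted p = 0.804). Cldn2, a pore-forming claudin, rose 7.69-fold, from 12.8 ± 7.92 to 98.6 ± 27.3 FPKM (SD, n = 2 each). Krt19 rose 3.49-fold, while Cldn15 fell 5.04-fold and Epcam 2.29-fold. Without control replicate 2 these 4 had limma adjusted p-values of 0.0660, 0.0731, 0.0656 and 0.114. Epcam lost its call whichever library was left out (up to 0.124). Cldn2 lost it without either double knockout replicate too (0.0817 and 0.0640), Krt19 without control replicate 1 (0.0734) or double knockout replicate 2 (0.0644), and Cldn15 without control replicate 1 (0.0603).

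**Figure D3:**
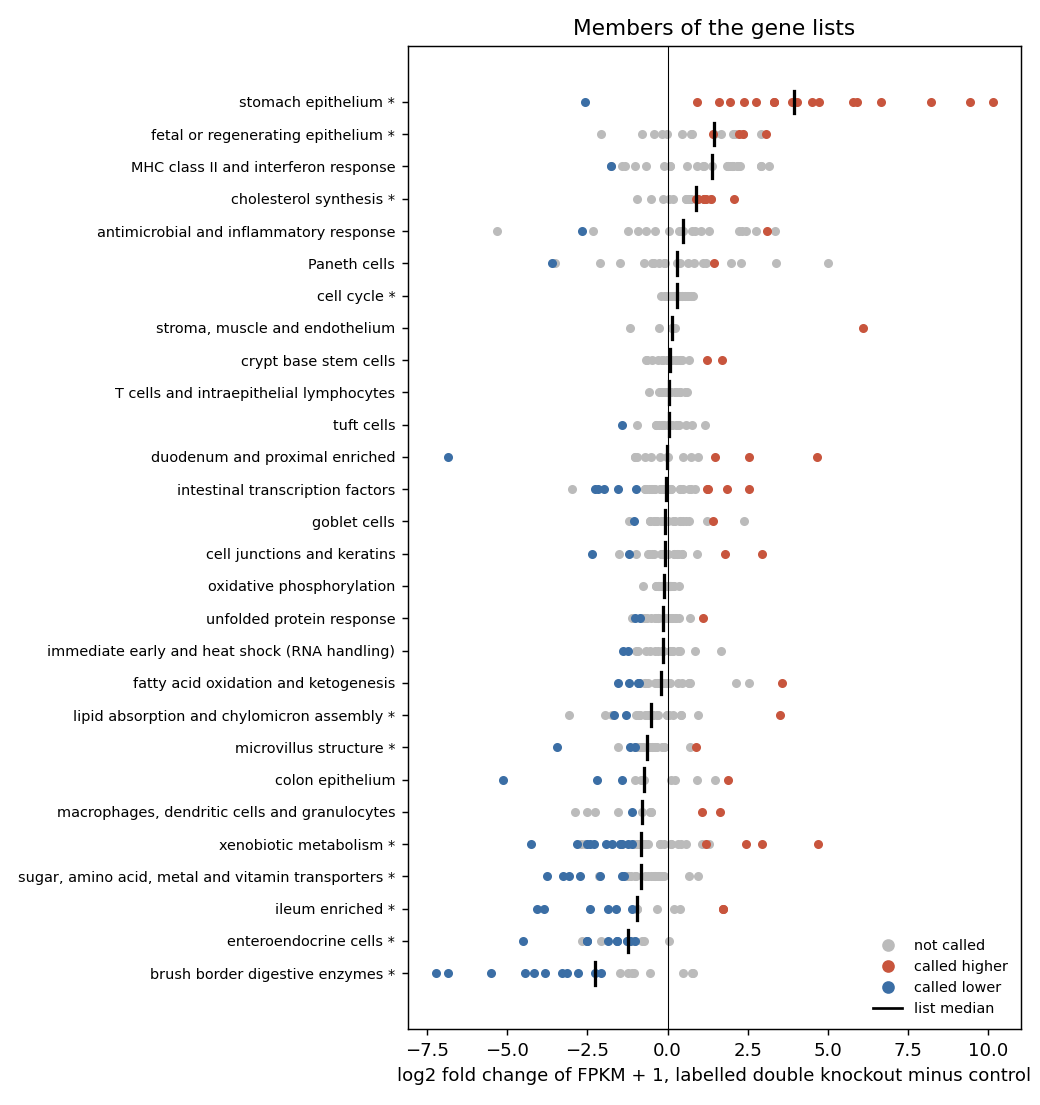
Log2 fold change of FPKM + 1, labelled double knockout minus control, for each tested member of the 28 lists tested; colours mark members called higher, lower or not called, black bars are list medians and asterisks mark the 11 lists called by camera with the preset correlation. Medians run from -2.25 for brush border enzymes to 3.95 for stomach epithelium. With an estimated correlation camera called 0 lists, but that version has little power with 4 libraries (lowest unadjusted p = 0.0624).

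In the unfolded protein response list 2 fell and 1 rose of 27 (6 lower and 1 higher adjusted over the list alone, camera, adjusted p = 0.0989), with Edem1 and Ddit3 2.05-fold and 1.87-fold lower. In the list of immediate early and heat shock genes, which respond to tissue handling, 2 fell of 19 with the same count adjusted over the list alone (camera, adjusted p = 0.299), with Hsph1 and Btg2 2.69-fold and 2.45-fold lower. The calls of Edem1, Ddit3 and Btg2 were lost whichever library was left out (limma, adjusted p of up to 0.142, 0.129 and 0.0965), and that of Hsph1 in each such fit except the 1 without double knockout replicate 2 (up to 0.0769). The unfolded protein response list was called lower without double knockout replicate 1 (camera, adjusted p = 0.00775). In oxidative phosphorylation limma called 0 of 49, over all genes or adjusted over the list alone, with 1 lower at an unadjusted p under 0.05 (camera, adjusted p = 0.355); the most abundant member, Atp5g3, stood at 1716 and 1401 FPKM. That list was called lower without control replicate 1 (camera, adjusted p = 0.0113). In the antimicrobial and inflammatory list Ccl20 rose 10.1-fold and Nlrp6 fell 6.31-fold, 1 each of 21 with the same counts adjusted over the list alone (camera, adjusted p = 0.528); both calls were lost without control replicate 2 (limma, adjusted p = 0.0656 and 0.104), that of Ccl20 also without either double knockout replicate (0.1001 and 0.0788) and that of Nlrp6 without control replicate 1 (0.0918). The list was called higher without double knockout replicate 2 (camera, adjusted p = 0.0241). In the list of MHC class II and interferon genes H2-DMa fell 4.62-fold, 1 of 27, with 0 called adjusted over the list alone (camera, adjusted p = 0.299, higher); its limma adjusted p was 0.164 without control replicate 2, 0.126 without control replicate 1 and 0.0627 without double knockout replicate 1. Without double knockout replicate 1 this list was called higher (camera, adjusted p = 7.87e-11).

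Markers of other cell types that an epithelial preparation can hold were measured beside these groups. Of 18 tested T cell and intraepithelial lymphocyte genes limma called 0, over all genes, adjusted over the list alone or at an unadjusted p under 0.05 (camera, adjusted p = 0.804); Gzma stood at 47.2 ± 5.59 and 70.8 ± 50.5 FPKM (SD, n = 2 each). The T cell list was called higher without double knockout replicate 1 (camera, adjusted p = 0.00775) and lower without double knockout replicate 2 (camera, adjusted p = 0.0403). Among 11 macrophage, dendritic cell and granulocyte genes 2 rose and 1 fell (2 higher and 4 lower adjusted over the list alone, camera, adjusted p = 0.0989, lower); Mrc1 rose from 0.181 to 2.65 FPKM and Cd14 from 3.81 to 9.18, with limma adjusted p-values of 0.0707 and 0.115 without control replicate 2. Mrc1 also lost its call without control replicate 1 (0.0754), and Cd14 whichever library was left out (up to 0.164). That list was called lower without control replicate 1, with no filter on low values, with FPKM of each library alone and with the replicate block (camera, adjusted p = 0.000491, 0.0137, 0.0257 and 0.0362). Among its 11 tested members 9 had a log2 fold change below 0 and 2 above (median -0.79). Under the filter lay 16 of its 27 members in the table, and Mrc1 passed with a control mean under 1 FPKM. Of the 6 stromal, muscle and endothelial genes tested Lyve1 alone was called, also adjusted over the list alone (camera, adjusted p = 0.434). The other 26 of 32 members lay under the filter. Among these Pecam1 and Prox1, chosen after their values were seen, did not exceed 0.447 and 0.983 FPKM in any library. The remaining lists had too few tested members for a list test. Under the filter lay 16 of 20 exocrine pancreas genes, 15 of 16 genes of B cells and plasma cells and 5 of 8 erythrocyte rows. Of the 4 exocrine pancreas genes tested Ctrb1, a chymotrypsinogen, rose from 0.319 ± 0.145 to 32.2 ± 25.3 FPKM (SD, n = 2 each, limma, adjusted p = 0.0164), with 2 higher and 1 lower adjusted over the list alone; without either control its adjusted p was 0.0897 and 0.0962. Igj, the 1 tested gene of B cells and plasma cells, stood at 1.04 and 3.09 FPKM (limma, adjusted p = 0.0723), and was called higher adjusted over the list alone. Of the 3 erythrocyte rows limma called 0, also adjusted over the list alone or at an unadjusted p under 0.05; the joined row of Hbb-b1 and Hbb-bs stood at 3.82 and 5.60 FPKM.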

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

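The alternatives were chosen before the data were examined. Of the 1041 genes called here, 855 were tested with a filter of 5 FPKM and 1019 with FPKM of each library alone. Every other refitted setting tested 1041. Among those tested 0 changed sign. The groups of each called gene did not overlap, so only another scaling or another source of FPKM could have turned a sign. Where 1 library was left out, the lone library of its group is assumed to vary like the other group; the calls then ranged from 171 to 693 genes, 67 to 309 higher and 97 to 384 lower, with fewer libraries in each fit. Leaving out a library gave log2 fold changes of 1.17 to 1.29 for Cdx2 and -2.46 to -1.86 for Hnf4a. With no filter but a mean above 0, 16711 genes were tested and 268 were called higher, 439 lower; more genes were adjusted over. Called members were then 7 lower of 20 brush border enzymes, 3 higher of 22 cholesterol synthesis genes, 3 lower and 1 higher of 16 ileum enriched genes and 7 lower and 3 higher of 35 xenobiotic genes, and these lists kept their camera call. Under the other settings the count stayed within 1.5 times of 1041, from 786 with the replicate block to 1160 with robust empirical Bayes. The labels do not say whether the replicate numbers pair the samples. Deviations of same-numbered libraries correlated at -0.00481 across genes. This is 1 value over genes that are not independent, so it cannot show whether the samples were paired. The block called 310 higher and 476 lower. The list count was 0 with an estimated correlation, 2 with fry (stomach epithelium and ileum enriched) and 10 to 15 otherwise. Of the lists, 10 turned direction, 3 of them with a call in either fit: cell cycle (adjusted p = 0.527) and tuft cells (4.3e-05) without control replicate 2, and T cells (0.0403) without double knockout replicate 2. Over the fits without 1 library the adjusted p of these 3 ran from 3.04e-07 to 0.683, from 1.63e-05 to 0.898 and from 0.00775 to 0.963. The other 7 turned only where neither fit called them. In fits without 1 library their adjusted p ran from 0.288 to 0.728 for cell junctions and keratins, 0.0120 to 0.728 for crypt base stem cells, 0.239 to 0.830 for Paneth cells, 0.830 to 0.954 for goblet cells, 0.507 to 0.963 for duodenum enriched genes, 7.87e-11 to 0.439 for MHC class II and interferon genes and 0.0113 to 0.728 for oxidative phosphorylation. Goblet cells also turned with no filter (0.920), a filter of 5 FPKM (0.942), quantile normalization (0.990), the replicate block (0.944) and fry (0.475), and Paneth cells with FPKM of each library alone (0.784) and fry (0.912). Tuft cells turned with no filter (0.936), duodenum enriched genes with a filter of 5 FPKM (0.451) or FPKM of each library alone (0.784), and cell junctions with quantile normalization (0.990). Of the named genes 6 turned, 0 with a limma call in either fit. Quantile normalization and FPKM of each library alone gave log2 fold changes of 0.0576 and 0.0644 for Cdx1 and 0.0177 and 0.102 for Pcna. Without 1 library they ran from -0.20 to 0.14 for Cdx1, -0.0764 to 0.0962 for Gata4, -0.10 to 0.30 for Gata6, -0.27 to 0.11 for Pcna, -0.41 to 1.16 for Gzma and -0.58 to 1.11 for the joined row of Hbb-b1 and Hbb-bs. The cause was not tested. Of the 66 named genes called, 27 kept their call whichever library was left out. Leaving out Xist and Y-linked genes left 1041 calls, and the authors' q under 0.01 kept 1026 of their 1532. Depth is unknown, so its limit on low genes could not be stated.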

Other observations

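The tests of mucin genes, of the enterocyte share, of crypt cells and of overlapping genes were chosen after the result was seen, as were the pair ratios by distance. The other tests were fixed before, but for linked alleles the interval, and for Gast the reading of a listed 0 as undecided, were brought in after the values were seen. The count of neighbouring genes left out pairs that share a symbol prefix, rather than thinning each family within a neighbourhood as its rule had set. The genes in the next paragraphs were chosen after their values were seen, except those named in the report.

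Some genes stood out in 1 animal rather than in a group. Isg15, an interferon-induced gene, was at 767 FPKM in double knockout replicate 2 against 39.1 in replicate 1 and 22.0 and 22.7 in controls, and Ifit1 at 248 against 14.0, 19.4 and 10.1. Over the MHC class II and interferon list the median difference between those 2 libraries was 2.59 log2 units. Reg3b, an antimicrobial lectin, was at 22813 FPKM in double knockout replicate 1 and 57.7 in replicate 2, against 5024 and 665 in controls. Between the controls, the tuft cell list differed by a median of 1.74 log2 units, with Rgs13 at 14.3 and 64.0 FPKM, and Mcpt1, a mast cell protease, at 32.0 and 139 FPKM.

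Gene families grouped by symbol gave another view, on 128 families of at least 10 tested genes. Camera called 7 higher and 0 lower in the libraries labelled double knockout, and 0 with an estimated correlation (adjusted p = 0.987 for each of the 7). The aldo-keto reductase family (Akr) had 6 of 11 genes called higher at a median log2 fold change of 1.16 (camera, adjusted p = 0.0241), among them Akr1b8, at 308 and 306 FPKM against 11.9 and 14.8. Cytosolic ribosomal proteins (Rpl) had a median of 0.46 with 0 of 44 genes called by limma and 8 higher at an unadjusted p under 0.05 (camera, adjusted p = 1.89e-05).

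The rise of stomach genes could come from gastric tissue carried into the preparations. Against corpus mucosa, the proton pump genes Atp4a and Atp4b averaged 2.71 FPKM where Gkn1 and Gkn2 averaged 1046, or 0.259%, although Atp4a (0.240 and 0.153 to 6.72 and 3.95 FPKM) and Gif (0.407 and 0.216 to 3.01 and 5.35), genes of gastric glands, were themselves called higher. For antral mucosa, Gast (highest value 0 FPKM) met the level set beforehand against it but does not decide, because it was listed at 0 in all 4 libraries, as was Hmgcs1, a gene of most cells; yet the gastric mucins Muc5ac and Muc6, each above 0 in at least 1 library, reached no more than 0.00236% of the mean of Gkn1 and Gkn2 in the libraries labelled double knockout, which argues against mucosa of either region. The rise was present in both libraries labelled double knockout and did not rest on 1, since over the 17 members called higher they differed by a median of 0.592 log2 units. A call favours members alike in both libraries, but 0 of the 18 tested members went uncalled. A change of gene expression in the epithelium itself remains a hypothesis that was not itself tested. Only the other explanations were tested, on the same data in which the rise was found. The level of Cdx2 leaves open what the labels stand for.

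The fall of brush border enzymes could come from a lower share of enterocytes. That would lower all abundant enterocyte genes alike, yet the 10 most abundant lipid absorption genes had a median log2 fold change of -0.359 (median SE 0.365) against -2.25 for the enzymes, which argues against it as the whole cause. Dilution by crypt cells would do the same. The same comparison, with the lipid genes 1.90 log2 units above the enzymes, thus argues against it as the whole cause too and is not a second test. Whether crypt cells rose at all cannot be told apart, because the cell cycle list was called (camera, adjusted p = 0.0367), in a call that several alternatives ended, and the crypt base list was not (0.519). An effect of the genotype is also open.

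With a mixed background and 2 animals per group, part of the called genes may reflect strain alleles rather than the knockout. Called genes whose symbols differ in prefix were neighbours on the chromosome in 119 pairs. The median was 94 in 10000 shuffles (one-sided permutation p = 0.0028), and differing haplotypes would give such an excess. The ratio of observed to random pairs was 1.26 for neighbours. At 5, 20 and 50 genes apart, distances looked at only afterwards, it was 0.967, 0.935 and 0.847 (SD in shuffles 0.0907 to 0.0945). Haplotypes spanning many genes would raise the ratio at those distances too. The ratios therefore argue against long haplotypes as the whole source of the excess. Shorter haplotypes stay open, and neighbours regulated together would also give such pairs. Reads shared by overlapping genes do not account for all of the excess, which held without them (109 pairs against 89, one-sided permutation p = 0.0137). For alleles linked to the targeted loci, 12 of 134 genes within 5 Mb of Cdx2 or Hnf4a were called (8.96%, exact 95% interval 4.71 to 15.1) against 9.58% elsewhere (one-sided Fisher exact p = 0.640); that interval, without which the lower share would have counted against linked alleles, is too wide to decide, so these cannot be told apart.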
